A study of Homo sapiens with 658 samples.

How the data were processed

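The series holds single-cell RNA sequencing of 658 wells from 7 Fluidigm C1 captures of a human fibroblast line that carries lentiviral hTERT, a tetracycline repressor and a repressor-controlled human MYOD. Cells were taken from growth medium (0 h) or after 24, 48 or 72 h in differentiation medium (alpha-MEM with 2% horse serum and doxycycline at 2 µg/ml). Per the labels, wells were scored under a microscope for the number of cells and debris. The authors aligned reads with TopHat and quantified genes with Cufflinks on hg19 (no versions given), and the deposited table holds FPKM of 47192 genes in each well. Nothing was realigned. The label of each well gives its mapped fragments. Insulin, a BMP inhibitor and an LSD1 inhibitor are named in the series for some cultures but in no label of these samples.

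Before the data were examined, the wells to use, the tests, the gene lists, the alternatives and the rule for naming genes were fixed. Wells scored as holding 1 cell without debris and with at least 500000 mapped fragments were used: 483 of 533. Wells scored empty (99), with 2 cells (25) or with debris (1) were left out of the comparisons. Wells per culture numbered 95 at 0 h, 93 and 96 at 24 h, 88 and 96 at 48 h, and 94 and 96 at 72 h. Median mapped fragments per cell used were 1728341 at 0 h, 1318234 and 1346026 at 24 h, 1486754 and 1738260 at 48 h, and 2005876 and 1631592 at 72 h. A gene was taken as detected in a cell at an FPKM of at least 1. Shares of cells carry a 95% Wilson interval, which covers counting error only and is wide at 51 to 83 cells per culture: for MYOG in 11 of 66 cells it runs from 9.57 to 27.4%.

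Symbols were given to identifiers with a table of gene names on GRCh38, which matched 32925 of 47192 identifiers (69.8%), and 14267 stayed without a symbol. Since the files are on hg19, no coordinates are given. Older list symbols were resolved through synonyms (MYLPF to MYL11, DDX58 to RIGI), and UHRF1, NEFL and PECAM1 were not found in the table.

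For each culture the mean FPKM over its cells was taken and log2(mean + 1) was tested with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3, for the 13263 genes with a mean FPKM of at least 1 over the 7 cultures. All 7 cultures entered 1 fit with time as group, which left 3 residual degrees of freedom, and the lone 0 h culture was assumed to vary like the others. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. An added 1 FPKM understates the fold of a gene with low values, and genes listed at 0 in a group get no fold. Gene lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it, over the lists with at least 3 tested genes. Counts "over the list alone" repeat the adjustment among the members of 1 list.

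The sarcomere index of a cell was the mean log2(FPKM + 1) of the sarcomere list. Within each of the 6 differentiation cultures, Spearman correlations of each gene with the index were taken across cells after the effect of the number of genes detected was removed by ranks. Their Fisher z values were tested over the 6 cultures with limma, and a gene passed at adjusted p < 0.05 and a mean rho of at least 0.2 in size. It had to be detected in 10% or more of the cells, and members of the sarcomere list were left out. The 12 relations between list indices used an exact two-sided sign-flip permutation over the 6 cultures, with a smallest p of 0.03125.

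Genes named for 24 h against 0 h, 72 h against 0 h and 72 h against 24 h come from the 10 largest rises and 10 largest falls among those passing, with the same direction in every pair of cultures and an FPKM of at least 1 in 10% of the cells of the higher group. For the other comparisons up to 5 and 5 are named, for correlations up to 10 and 10. Genes of a fixed list are named with their list.

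Alternatives tried were a pseudocount of 0.1, no filter, the mean of log values, cells rescaled to a sum of 1000000, at least 1000000 fragments, wells with 1 or 2 cells, a replicate block, eBayes without a trend, and leaving out each culture in turn. Added after the values were seen were a run without cells above 90% mitochondrial FPKM or under 3000 genes detected, and a run with each culture centred on its median. The limma step on culture values was tested on simulated culture values with a normal spread. Single cells were not simulated, so the false calls do not cover atypical cells. Shifts of log2 1, 2, 3 and 4 were planted at 72 h against 24 h. Of these 4, 20, 82 and 98% were recovered, with 6 false calls among 13263 genes. For 24 h against 0 h the limma step recovered 2, 18, 78 and 96%. A change under 3 on the log2 scale was thus often missed. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.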

Results

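Human fibroblasts bought from a vendor and immortalised with hTERT were followed while a doxycycline-induced human MYOD drove them towards muscle. Single cells were captured from 7 cultures: 1 in growth medium (0 h, replicate 1 only) and 2 each after 24, 48 and 72 h in differentiation medium with doxycycline. Cells used numbered 63 at 0 h, 70 and 51 at 24 h, 74 and 76 at 48 h, and 66 and 83 at 72 h, 483 in all. Each culture filled 1 capture chip and gave 1 mean per gene, so every comparison has n = 2 cultures per group, or n = 1 at 0 h, and chip and culture cannot be told apart. Every "±" below is a SD over n = 2 cultures, unless another n is given.

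The scale of the values differed between times. The median FPKM sum per cell was 480563 at 0 h, 463693 and 455744 at 24 h, 503919 and 505862 at 48 h, and 674617 and 876413 at 72 h. The median number of genes detected per cell was 7454 at 0 h, 7286 and 6149 at 24 h, 6633 and 6315 at 48 h, and 6469.5 and 5478 at 72 h. The median log2 change of all tested genes was 0.74 from 24 to 72 h and 0.05 after each cell was rescaled to a sum of 1000000. With the mean of log values it was 0.04. As deposited, the median was 0.00 for 24 h against 0 h and 0.72 for 72 h against 0 h. It was 0.30 for 48 h against 24 h and 0.46 for 72 h against 48 h. A log2 change below should be read against the median of its comparison.

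Did the induced factor and its partners rise? MYOD1, the muscle-determining transcription factor that the transgene encodes, had a mean FPKM of 0.287 at 0 h, 2.99 ± 0.47 at 24 h, 4.81 ± 0.06 at 48 h and 4.72 ± 0.34 at 72 h. No comparison of MYOD1 passed the test: log2 change 1.63 at 24 h against 0 h (adjusted p = 0.629) and 2.15 at 72 h against 0 h (adjusted p = 0.0744). The table does not separate transgene from endogenous MYOD1 reads. MYOG, the factor that acts after MYOD1 to start terminal differentiation, was listed at 0 in every cell at 0 h and reached 1.56 ± 1.41 at 48 h and 9.51 ± 2.59 at 72 h. It rose at 72 h against 24 h by 3.37 (SE 0.63, adjusted p = 0.0197), and gave 3.41 (adjusted p = 0.0962) with rescaled cells. MEF2C, a MADS-box partner of the MYOD family, stood at 7.08 at 0 h, 30.4 ± 7.61 at 24 h, 58.6 at 48 h and 132 ± 32.7 at 72 h, and rose at 72 h against 24 h (2.08, adjusted p = 0.0298), but not with rescaled cells (1.56, adjusted p = 0.122).

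**Figure D1:**
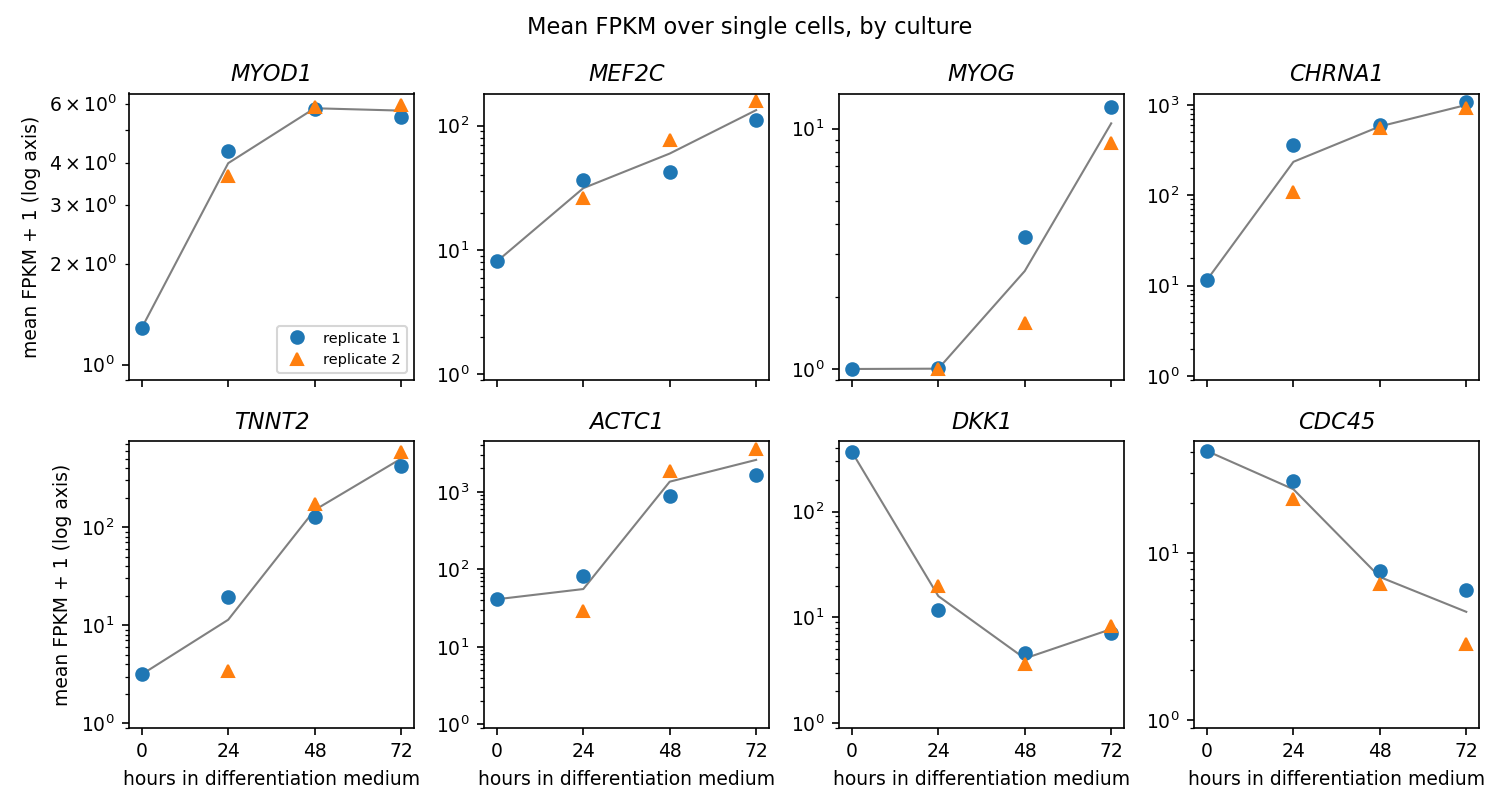
Mean FPKM + 1 (log axis) of 8 genes in each culture against hours in differentiation medium; circles are replicate 1, triangles replicate 2, and the grey line joins the means by time.

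What did the first 24 h change? MYMX (ENSG00000262179.2), the micropeptide that completes myoblast fusion, went from 0.0125 at 0 h to 29.8 ± 15.9 (SD, n = 2 cultures; log2 change 4.83, SE 0.62, adjusted p = 0.00157). CHRNA1, the alpha subunit of the muscle acetylcholine receptor, went from 10.6 to 234 ± 178 (4.11, SE 0.62, adjusted p = 0.00556), and KLHL41, which stabilises thin filaments, from 0.635 to 29.9 ± 15.7 (4.14, SE 0.58, adjusted p = 0.00345). ASS1 (ENSG00000130707.13), which makes argininosuccinate on the way to arginine, had the largest rise, from 4.53 to 158 ± 26.1 (4.84, SE 0.48, adjusted p = 0.000502), and was found in 30.2% of cells at 0 h and 99.2% at 24 h. The adaptor gene SHD (4.33, adjusted p = 0.0017) and the amino acid transporter gene SLC7A7 (3.61, adjusted p = 0.00914) also rose. With rescaled cells SLC7A7 gave 3.99 (adjusted p = 0.0585) and did not pass, while ASS1, MYMX, SHD, KLHL41 and CHRNA1 did. With the mean of log values ASS1 and CHRNA1 passed, and MYMX (3.08, adjusted p = 0.0946), SHD (2.17, adjusted p = 0.114), KLHL41 (3.11, adjusted p = 0.0703) and SLC7A7 (2.24, adjusted p = 0.255) did not. CCNA1 (3.74), IMPA2 (3.66), FITM1 (3.57) and AQP3 (3.51) rose too. With the mean of log values they gave 1.29, 1.48, 1.97 and 2.21, and none of the 4 passed. Without the 3 atypical cells described next these 4 kept their log2 changes (3.73, 3.64, 3.56 and 3.50) but did not pass, and with rescaled cells FITM1 passed, while CCNA1 (4.16), AQP3 (3.90) and IMPA2 (3.10) stayed about as large without passing.

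The falls at 24 h rested on few cells. Of 114 genes called at 24 h against 0 h, 21 rose and 93 fell, and the 93 include all 13 mitochondrial transcripts (median log2 change -4.76). In the 0 h culture, 2 cells held 93.6% and 93.4% mitochondrial FPKM, with FPKM sums of 12685796.5 and 55673854.4. At 48 h, 1 cell with 1843 genes detected and no mitochondrial FPKM also stood apart. Without these 3 cells 10 genes were called, 7 higher and 3 lower, and no mitochondrial transcript passed. Among the 10 largest falls, MT-CO1 went from -5.22 to -0.27, MAP3K4 from -5.17 to -0.77, USP37 from -5.01 to -0.71 and SPATA13 from -5.73 to -0.23. MT-ND4, NAPRT, EML5, MT-ND2 and MTCO3P12 (-5.13 to -4.94) changed sign. The test was limma on 13263 genes, with 912 genes at unadjusted p < 0.05. The lone 0 h culture was assumed to vary like the others, and without 24 h replicate 2 the count was 31.

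By list, the 4 muscle sets moved up at 24 h. Of 17 tested myogenic regulators 0 rose and 0 fell (2 and 0 when adjusted over the list alone), with a median of 0.65 and 16 of 17 higher, MEF2C (1.94, adjusted p = 0.23) among them. As a set they moved up by camera (adjusted p = 2.0e-05, adjusted p = 0.227 with an estimated correlation). Of 18 sarcomere genes 2 rose (2 and 0 over the list alone): TNNT1, a slow troponin T, from 4.49 to 39.3 ± 8.38, and KLHL41. TNNT1 was not called without the atypical cells, nor with rescaled cells. The list median was 0.27, and the set moved up by camera (adjusted p = 0.00811, adjusted p = 0.445 with an estimated correlation). Of 15 excitation and neuromuscular junction genes 2 rose (2 and 0 over the list alone): CHRNA1, and SGCA, which encodes alpha-sarcoglycan, from 1.11 to 13.9 ± 2.25. SGCA was not called without the atypical cells. The list median was 1.16, and the set moved up by camera (adjusted p = 6.3e-07, adjusted p = 0.341 with an estimated correlation). Of 15 fusion and adhesion genes MYMX alone rose (1 and 1 over the list alone), median 0.39, set up (adjusted p = 0.0467, adjusted p = 0.445 with an estimated correlation).

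Sterol and interferon genes also stood higher at 24 h as sets, with no single gene passing. Of 24 cholesterol synthesis genes 23 were higher (median 1.32; SQLE, an oxidising step of the pathway, 2.32, adjusted p = 0.233; camera adjusted p = 6.2e-10, adjusted p = 0.411 with an estimated correlation). Of 28 interferon response genes 27 were higher (median 1.44; IFIT1 2.13, adjusted p = 0.44; camera adjusted p = 4.4e-10, adjusted p = 0.445 with an estimated correlation). The p53 and stress list (27 genes, median 0.53) and the cell cycle exit list (21 genes, median 0.52, 2 and 0 over the list alone; CCND3 2.64, adjusted p = 0.0693) moved up by camera, at 0.0247 and 0.0467 (adjusted p = 0.341 and adjusted p = 0.50 with an estimated correlation), with 0 genes called in each.

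Of 33 S-phase genes 29 were lower at 24 h (median -0.55, 0 called; camera adjusted p = 0.00289, adjusted p = 0.275 with an estimated correlation). Of 20 TGF-beta and smooth muscle genes 16 were lower (median -0.95), 1 of them called (0 and 3 over the list alone). TPM1, a tropomyosin of smooth and skeletal muscle, did not pass (-2.33, adjusted p = 0.108). The set moved down (camera adjusted p = 5.3e-06, adjusted p = 0.343 with an estimated correlation). The mitochondrial set moved down (adjusted p = 3.1e-54, adjusted p = 0.183 with an estimated correlation), and gave a median of 0.30 and adjusted p = 0.205 without the 3 atypical cells. These were 8 sets up and 3 down of 11 called. The other sets did not pass at 24 h: G2/M (median -0.20), BMP and ID (-0.07), insulin and IGF (0.10), fibroblast matrix (-0.19), Notch (0.25), immediate early (0.25), ribosomal proteins (0.17), oxidative phosphorylation (0.21), neural (0.03) and keratinocyte (0.73). Chromatin regulators (29 genes) had a median of 0.06 and a mean of the other sign, and did not pass. In the matrix list POSTN, a matricellular protein, fell (-3.68, adjusted p = 0.0331), but not without the 3 atypical cells.

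What changed between 24 and 72 h, at the same medium? TNNT2 (ENSG00000118194.14), the cardiac and embryonic troponin T, went from 10.4 ± 11.3 to 498 ± 111 (SD, n = 2 cultures; log2 change 5.92, SE 0.66, adjusted p = 0.0011). The fast regulatory light chain gene MYL11 (ENSG00000180209.7) went from 1.55 ± 0.513 to 150 ± 2.6 (5.89, SE 0.49, adjusted p = 0.000186), the slow troponin I gene TNNI1 from 0.838 ± 1.18 to 83.8 ± 3.47 (5.69), and ACTC1, the actin of developing muscle, from 54.6 ± 38.3 to 2582 ± 1326 (5.63, SE 0.57, adjusted p = 0.000517). H19 (ENSG00000130600.10), the imprinted non-coding RNA of embryonic tissues, had the largest rise, from 5.72 ± 5.46 to 579 ± 107 (6.71, SE 0.59, adjusted p = 0.000212). IGF1, the growth factor of muscle hypertrophy, went from 0.0317 ± 0.00249 to 40.4 ± 12.5 (5.29, adjusted p = 0.00146). The matrix genes ABI3BP (5.94), LUM (6.13; 35.9 ± 47.9 to 1242 ± 996) and DCN (5.42; 18.4 ± 25.1 to 363 ± 205) rose as well, as did the pseudogene ABRAXAS1P1 (6.11). With rescaled cells LUM (5.44, adjusted p = 0.10) and DCN (4.81, adjusted p = 0.144) kept most of the rise but did not pass.

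Among the falls, MMP1, the gene of the interstitial collagenase, went from 328 ± 52.9 to 33.9 ± 42.8 (SD, n = 2 cultures; -4.23, SE 0.86, adjusted p = 0.023) and was found in 94.2% of cells at 24 h and 6.04% at 72 h. The focal adhesion adaptor gene LPXN fell by 3.46 (SE 0.49, adjusted p = 0.0066; 81.8% of cells to 14.1%), and the syndecan gene SDC1 by 2.86 (79.3% to 9.4%). TM4SF1 (-4.04), PRSS3 (-3.73), the stromelysin gene MMP3 (-3.38), MYEOV (-2.99), MLPH (-2.98), TMEM40 (-2.72) and the non-coding LASTR (-2.71) fell as well. With rescaled cells 13 of the 20 genes named for this comparison passed, and 7 did not. Among these 7 the rescaled falls were larger than as deposited (MMP1 -5, TM4SF1 -4.36, MMP3 -4.10, LASTR -3.53, TMEM40 -3.36).

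In all 790 genes were called at 72 h against 24 h by limma, 748 higher and 42 lower (94.7% higher), against a median of all tested genes of 0.74. With rescaled cells 39 were called, 28 higher and 11 lower (71.8% higher), and with each culture centred on its median 98, 47 higher and 51 lower. With the mean of log values 605 were called, 270 higher and 335 lower. The count was 0 without 72 h replicate 2 (2291 genes at unadjusted p < 0.05) and 1277 without 72 h replicate 1.

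**Figure D2:**
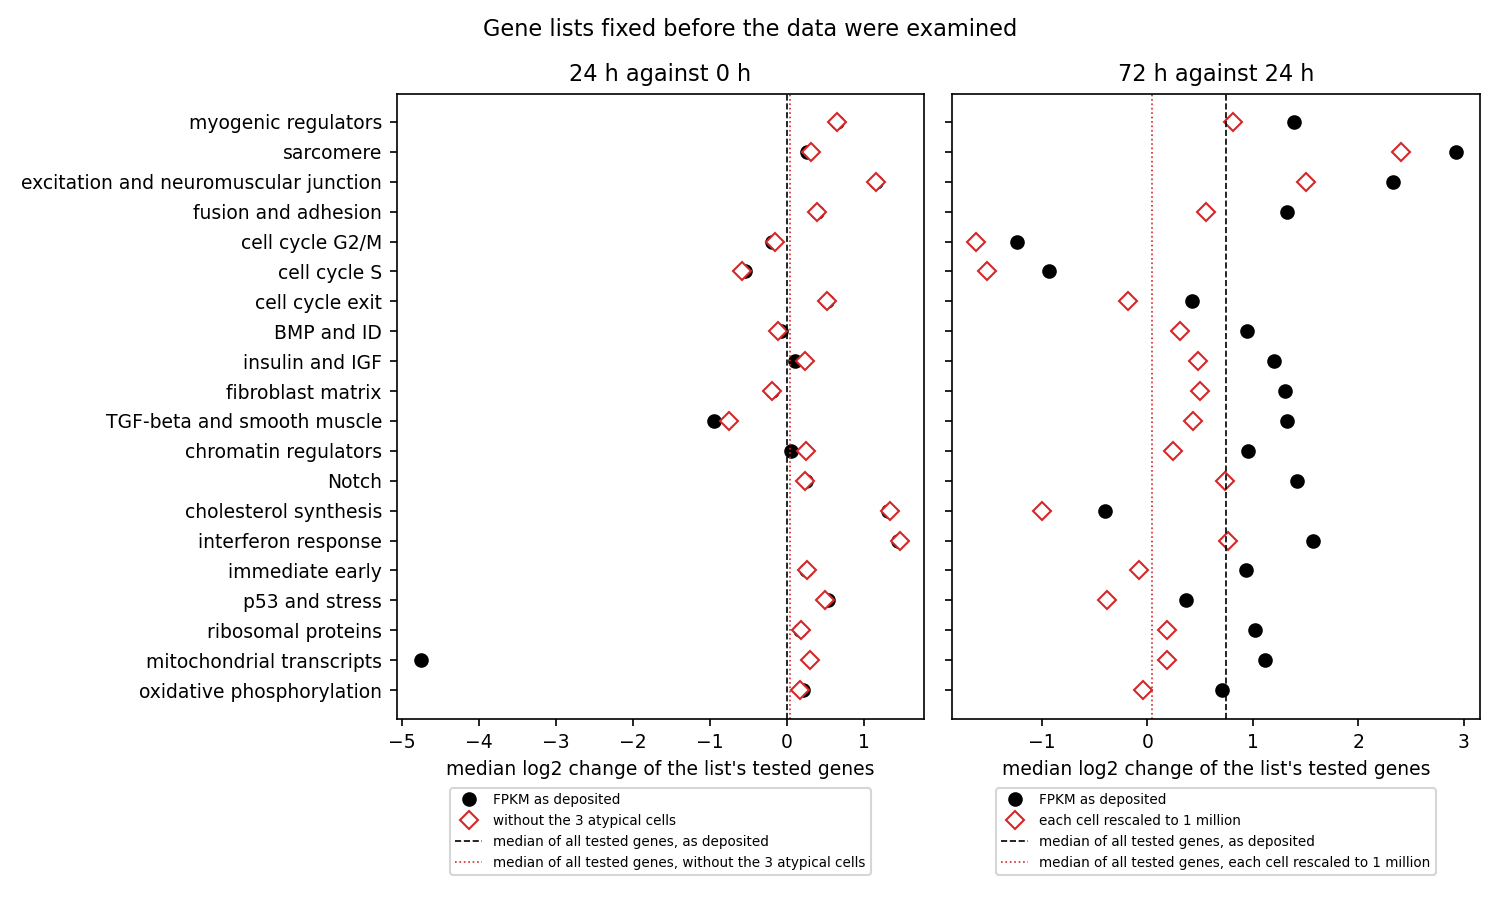
Median log2 change of the tested genes of each list at 24 h against 0 h (left; red diamonds without the 3 atypical cells) and at 72 h against 24 h (right; red diamonds with each cell rescaled to 1000000). Dashed lines mark the median of all tested genes.

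The contractile list had the largest median at 72 h against 24 h. Of 18 sarcomere genes 12 rose and 0 fell (14 and 0 when adjusted over the list alone; median 2.92, rescaled 2.40). They include the troponin genes TNNT3 (35.7 ± 18.9 at 72 h, listed at 0 at 24 h), TNNC2 (4.13) and TNNI2 (3.22), and the embryonic light chain gene MYL4 (4.75). The embryonic myosin heavy chain gene MYH3 (1.02, adjusted p = 0.3), NEB (0.75) and TPM2 (0.79) did not pass. With rescaled cells 8 of the list were called. The set moved up by camera (adjusted p = 2.5e-12, adjusted p = 0.265 with an estimated correlation). Of 15 excitation and neuromuscular junction genes 9 rose (11 and 0 over the list alone; median 2.33, rescaled 1.5), among them MUSK, the receptor kinase that organises the synapse (2.85 ± 0.196 to 44.3 ± 9.13), CHRNA1 (2.33), CHRNG (3.39), ENO3 (3.73) and DES (3.44). With rescaled cells 2 of the 9 were called, STAC3 and MUSK. CKM, the muscle creatine kinase gene, did not pass (2.09, adjusted p = 0.0607). The set moved up (adjusted p = 3.0e-06, adjusted p = 0.331 with an estimated correlation).

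Of 17 myogenic regulators 6 rose (9 and 0 over the list alone; median 1.39, rescaled 0.81), among them MYOG, MEF2C, the E-protein genes TCF12 (2.29) and TCF4 (1.89), and the splicing regulator gene RBM24 (2.15). With rescaled cells 0 of these were called. The set moved up (adjusted p = 0.0211, adjusted p = 0.331 with an estimated correlation). Of 15 fusion and adhesion genes 5 rose (6 and 0 over the list alone; median 1.32, rescaled 0.56): MYMX (2.31), JAM2 (3.26), JAM3 (2.32), ADAM12 (2.36) and ANXA5 (1.58). With rescaled cells 0 of the 5 were called. That set passed as deposited (adjusted p = 0.0409, adjusted p = 0.458 with an estimated correlation) and did not with rescaled cells (0.0546). Of 10 Notch genes HEYL, a Notch target, rose (3.19, not called with rescaled cells; 5 and 0 over the list alone; median 1.41, rescaled 0.73; camera adjusted p = 0.013, adjusted p = 0.331 with an estimated correlation).

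Cell cycle lists stood lower at 72 h while most other genes stood higher. All 36 G2/M genes were lower than at 24 h (median -1.23, rescaled -1.63), 0 were called, also over the list alone, against 28 with the mean of log values, and the set moved down (adjusted p = 1.0e-27, adjusted p = 0.331 with an estimated correlation). Of 33 S-phase genes 27 were lower (median -0.94, rescaled -1.52), and 2 fell (2 over the list alone): the replicative helicase genes MCM5 (22.3 ± 0.581 to 4.65 ± 0.0575; -2.04, adjusted p = 0.0343) and CDC45 (23 ± 4.14 to 3.44 ± 2.25; -2.52, adjusted p = 0.027). With the mean of log values 14 were called. This set moved down (adjusted p = 5.9e-19) and was the only one that also passed with an estimated correlation (adjusted p = 0.0484), though not with rescaled cells (0.344), where 0 of its genes were called. Of 21 cell cycle exit genes 3 rose (6 and 0 over the list alone), CDKN1C, an inhibitor of cyclin-dependent kinases (3.71; 1.08 to 26.1 ± 7.19), CCND2 (2.51) and BTG1 (1.88), and 0 with rescaled cells. The list median was 0.42, below that of all genes and -0.19 rescaled, and the set did not pass (adjusted p = 0.377).

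Of 26 insulin and IGF genes 7 rose (10 and 0 over the list alone; median 1.20, rescaled 0.48, camera adjusted p = 0.0684): IGF1, IGF2 (4.26; 0.335 to 24.2 ± 4.86), IGF1R (2.66), PIK3R3, FOXO1 (2.89), FOXO3 and PDK4. Of the 7, IGF1 alone was called with rescaled cells. Of 20 TGF-beta and smooth muscle genes 5 rose (11 and 1 over the list alone; median 1.33, rescaled 0.43, adjusted p = 0.0802): ACTA2, the smooth muscle actin gene (2.83; 12.3 to 89.6 ± 10.5), TPM1 (2.18), TGFB2, TGFB3 (3.53) and SKIL, of which SKIL alone was called with rescaled cells. Of 19 BMP and ID genes 0 were called, also over the list alone (median 0.94, rescaled 0.31, adjusted p = 0.902). ID1 and ID3, which encode inhibitors of MYOD family dimers, gave -0.92 and 0.60. Of 29 chromatin regulators TET2 (2.41) and SETD7 (2.14) rose (2 and 0 over the list alone, 0 with rescaled cells; median 0.95, adjusted p = 0.953). KDM1A, the gene of the LSD1 demethylase, did not pass (0.49).

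Of 37 fibroblast matrix genes 10 rose and 0 fell (16 and 0 over the list alone; median 1.31, rescaled 0.50), with COL1A2 (158 to 752 ± 470), COL3A1 (20.3 to 109 ± 49), FBN1 and TNC among them; COL1A1 did not pass (0.54). With rescaled cells 0 of the 10 were called. The matrix set passed as deposited (adjusted p = 0.0423, adjusted p = 0.598 with an estimated correlation) and did not with rescaled cells (0.0712). Of 28 interferon response genes 5 rose (11 and 0 over the list alone; 27 of 28 higher, median 1.57, rescaled 0.76), such as IFIT2 (2.84), STAT2 (2.48) and IFIH1 (2.42), and 0 with rescaled cells. The set moved up (adjusted p = 0.00875, adjusted p = 0.64 with an estimated correlation). Of 24 cholesterol genes 0 were called (median -0.40, rescaled -1) and the set moved down (adjusted p = 9.3e-07, adjusted p = 0.458 with an estimated correlation).

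Of 43 ribosomal protein genes RPL3 rose (19 and 0 over the list alone; median 1.02, rescaled 0.19; camera adjusted p = 7.8e-05, adjusted p = 0.598 with an estimated correlation). Of 13 mitochondrial transcripts 0 rose (10 and 0 over the list alone; median 1.11, rescaled 0.19; adjusted p = 0.00875, adjusted p = 0.598 with an estimated correlation, and 0.17 with rescaled cells). Of 33 oxidative phosphorylation genes SDHD, COX7A1 and PPARGC1A, the coactivator of mitochondrial biogenesis (3.26), rose (3 and 0 over the list alone; median 0.70, rescaled -0.04, adjusted p = 0.206). Of 22 immediate early genes FOS, EGR1 (3.47), EGR2 and DUSP1 rose (4 and 0 over the list alone; median 0.94, rescaled -0.08, adjusted p = 0.377), and of 27 p53 and stress genes TP53INP1 rose (2.87; 2 and 0 over the list alone; median 0.36, rescaled -0.38, adjusted p = 0.206). None of the genes named in this paragraph was called with rescaled cells.

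Markers of other cell types were mostly absent. No adipocyte marker was tested, and the endothelial (TEK -0.63), blood (CD68 -2.32, adjusted p = 0.0798), melanocyte (MITF 2.90, adjusted p = 0.0237) and bone (RUNX2 1.05, SPP1 -1.74) lists had 1, 1, 1 and 2 tested genes, too few for a set test. MITF rose, but was not called with rescaled cells, and neither was KRT18 below. Of 4 neural markers 0 were called (1 and 0 over the list alone; median 0.40, rescaled -0.74; adjusted p = 0.377). Of 3 keratinocyte markers KRT18, a simple-epithelium keratin also made by cultured fibroblasts, fell (-2.13, adjusted p = 0.0331; 0 and 1 over the list alone), KRT8 gave 0.12, and the set moved down (adjusted p = 0.00819, adjusted p = 0.366 with an estimated correlation). The camera calls at 72 h against 24 h numbered 13, 9 up and 4 down, and 8 without 24 h replicate 1.

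How did the end point differ from growth medium? KLHL41 (7.34, SE 0.58, adjusted p = 0.000111; 0.635 to 270 ± 82.8, SD, n = 2 cultures), TNNT2 (7.29), SHD (7.22), MYMX (7.14), MYL11 (7.11), H19 (7.07), the myokine precursor gene FNDC5 (6.54), the small heat shock gene HSPB3 (6.51) and CHRNA1 (6.44) were the largest rises. ABRAXAS1P1, listed at 0 at 0 h, rose too. The falls included genes of secreted regulators and proteases, such as DKK1, a secreted Wnt antagonist (-5.57, SE 0.62, adjusted p = 0.000494; 366 to 6.74 ± 0.82; 98.4% of cells to 8.05%). MMP1 (-5.39), TM4SF1 (-5.17), SERPINB7 (-5.16), SH2D5 (-4.80), PRSS3 (-4.75), SPATA13 (-4.68), EVA1A (-4.49) and LASTR (-4.41) fell as well. With rescaled cells MMP1 (-6.36, adjusted p = 0.067) and EVA1A (-4.10, adjusted p = 0.103) kept falls of that size but did not pass. Without the atypical cells SPATA13 changed sign and EVA1A went from -4.49 to -3.37. SH2D5, found in 11.1% of cells at 0 h, no longer reached the filter on low values in that run, nor with rescaled cells. With the mean of log values SH2D5 gave -0.35 (adjusted p = 0.101).

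In the cell cycle exit list 7 of 21 genes rose at 72 h against 0 h, CDKN1C (4.28), BTG1 (3.88), CCND3 (3.33), BTG2 (3.32), CCND2 (3.03), CDKN2C (2.91) and RBL2, and 1 passed with rescaled cells. The exit set did not pass (14 of 21 higher, median 0.84, centred 0.03; camera adjusted p = 0.649), and 4 of its genes were called higher and 5 lower with the mean of log values. All 36 G2/M genes were lower (median -1.49) and CDC20 (-3.73) and NUF2 (-3.07) fell; 0 of the list were called with rescaled cells, 1 without the atypical cells and 32 with the mean of log values. In the S list CDC45 (-3.29), CDC6 (-3.12), DTL (-2.33) and MCM5 (-2.27) fell (7 of the list with rescaled cells, 5 without the atypical cells, 29 with the mean of log values). CDH2, the N-cadherin gene, fell from 19.5 to 0.737 ± 0.223 (-3.57, adjusted p = 0.0126), while the M-cadherin gene CDH15 rose (2.92). Of the interferon list 13 rose (median 2.92), with IFI44L (4.74), GBP2 (4.73) and STAT2 (4.47), and 2 with rescaled cells. In all 974 genes were called by limma, 803 higher and 171 lower (82.4% higher; 3409 at unadjusted p < 0.05), 866 without the 3 atypical cells (810 higher and 56 lower) and 329 with rescaled cells (245 higher and 84 lower). The split turned under other settings: 299 higher and 367 lower with centred cultures, 466 and 964 with the mean of log values, and 168 and 606 with no filter. All 13 mitochondrial transcripts are among the 171, and none is among the 56. Leaving out 72 h replicate 2 gave 182 and leaving out 72 h replicate 1 gave 1399, and 0 h is 1 culture.

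Which genes moved first after 24 h? Between 24 and 48 h 8 genes rose and 1 fell of 13263 tested by limma (1311 at unadjusted p < 0.05). ACTC1 (4.70, SE 0.57, adjusted p = 0.0174; 1350 ± 680 at 48 h, SD, n = 2 cultures), H19 (4.42), ABRAXAS1P1 (4.35), TNNT2 (4.18) and the retinal reductase gene DHRS3 (4.12; 0.694 ± 0.683 to 27.5) rose. Of the sarcomere list 3 rose (11 and 0 over the list alone; median 1.59), and all 36 G2/M genes were lower (median -1.30) with 0 called. Over the list alone 9 excitation and neuromuscular junction genes were called higher and 2 S-phase genes lower. Camera called the sarcomere (adjusted p = 1.9e-12), excitation and myogenic sets up and the G2/M, S, cholesterol and keratinocyte sets down. With an estimated correlation the S set alone passed (adjusted p = 0.0489 with an estimated correlation, 0.307 rescaled). With rescaled cells none of the 5 named genes passed (0 of all genes; adjusted p = 0.0542 to 0.102), although their log2 changes stayed as large (ACTC1 4.36, H19 4.82, ABRAXAS1P1 4.78, TNNT2 4.33, DHRS3 4.38), and leaving out 1 culture gave 0 genes, or 17 without 24 h replicate 1. Between 48 and 72 h limma called 1 gene (1252 at unadjusted p < 0.05), which has no symbol in the reference, and 0 when any 1 culture was left out. No list member passed (over the list alone 5 sarcomere, 3 insulin and IGF, and 2 TGF-beta and smooth muscle genes, all higher). Camera called the sarcomere (adjusted p = 1.7e-05), ribosomal, oxidative phosphorylation and interferon sets up and the G2/M and S sets down, and none with an estimated correlation (adjusted p = 0.766 for the sarcomere). Down here is against the other genes only. The S list had a median of 0.19 with 20 of 33 genes higher, and G2/M a median of -0.02 with 16 of 36 higher. With rescaled cells the sarcomere, ribosomal and interferon sets passed.

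How many cells expressed muscle genes? At 72 h 94.4 ± 2.8% (SD, n = 2 cultures) of cells had TNNT2 at an FPKM of at least 1, against 6.35% at 0 h, 21.4 ± 8.1% at 24 h and 93.3 ± 2.01% at 48 h. ACTC1 was found in 20.6%, 44.3 ± 18.2%, 96 ± 3.85% and 100% of cells, and MEF2C in 49.2%, 72.4%, 82.5% and 91.2%. MYOD1 was found in 12.7% of cells at 0 h, 46.9 ± 16.5% at 24 h, 70.0 ± 2.26% at 48 h and 47.4 ± 2.79% at 72 h. MYOG was far rarer: 0 of 63 cells at 0 h at that FPKM (upper limit of the interval 5.75%), 0 of 70 and 0 of 51 at 24 h (5.20% and 7%), 9.46% and 6.58% at 48 h, and 16.7% (11 of 66; interval 9.57 to 27.4%) and 10.8% (9 of 83; 5.81 to 19.3%) at 72 h, a mean of 13.8 ± 4.12%. MYH3 was found in 54% of cells at 0 h and 47.3% at 72 h, CKM in 4.68 ± 0.194% at 72 h, TTN in 3.48%, and MYF5 and MYH8 in no cell of any culture.

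Proliferation markers were found in smaller shares of cells at 48 and 72 h than at 0 and 24 h. MKI67, the antigen of cycling nuclei, was found in 98.4% of cells at 0 h, 78.5 ± 0.099% at 24 h, 33.8 ± 19.2% at 48 h and 19.8 ± 12.7% at 72 h (SD, n = 2 cultures), CDK1 in 85.7%, 63.3 ± 4.71%, 41.8 ± 20.9% and 23.1 ± 12.3%, and TOP2A in 92.1%, 80.2%, 47 ± 37.8% and 31.9 ± 12.7%. The replicates differed after 48 h: in replicate 1 all 3 shares were larger at 72 h than at 48 h (MKI67 20.3% and 28.8%, CDK1 27.0% and 31.8%, TOP2A 20.3% and 40.9%). ID1 was found in 90.5% of cells at 0 h and 51.7 ± 8.34% at 72 h, ID3 in 98.4% and 97.7%, and COL1A1 in 100% and 87.9 ± 0.0516%. These shares are descriptions without a test, and the intervals cover counting error only. Wells scored empty also held these transcripts, at times in shares or levels like those of 1-cell wells. At 72 h 3 of 3 such wells over the fragment minimum had ACTC1 and TNNT2, 1 of 3 had MYOD1 and 1 of 3 MYOG. In 1-cell wells these were 149, 141, 71 and 20 of 149. Median FPKM at 72 h, empty and 1-cell, was 2037 and 1109 for ACTC1, 476 and 281 for TNNT2, and 0.315 and 0.906 for MYOD1. CDK1 was in 15 of 21 empty and 76 of 121 1-cell wells at 24 h, and in 5 of 5 and 63 of 150 at 48 h. At 0 h it was in 1 of 6 and 54 of 63, and at 72 h in 0 of 3 and 33 of 149. MYOD1 at 24 h was in 5 of 21 and 59 of 121.

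**Figure D3:**
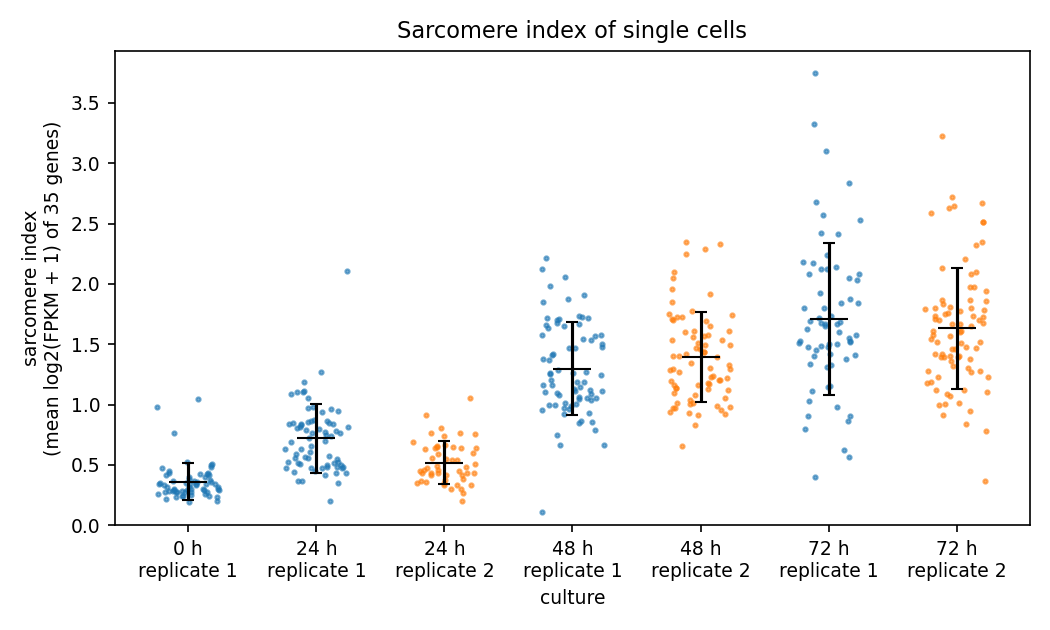
Sarcomere index (mean log2(FPKM + 1) of the sarcomere list) of each cell in the 7 cultures; bars are means and error bars SD over cells.

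Which genes varied with the contractile programme among cells of the same culture? The sarcomere index averaged 0.36 at 0 h, 0.72 and 0.52 at 24 h, 1.30 and 1.40 at 48 h, and 1.71 and 1.63 at 72 h. The muscle selenoprotein gene SELENOW (mean rho 0.444 ± 0.158, SD, n = 6 cultures), the intermediate filament gene NES (0.426 ± 0.132), the light chain gene MYL6 (0.414 ± 0.113), the calponin gene CNN3 (0.403), COX7A1 (0.390), the muscle cofilin gene CFL2 (0.386), CHRNA1 (0.382), NEXN (0.382) and TPM1 (0.379) were among the highest correlations, positive in 6 of 6 cultures. TNFAIP6, an inflammation-induced hyaluronan-binding protein (-0.294 ± 0.16), the chemokine gene CXCL8 (-0.218), PLAUR, the urokinase receptor gene (-0.205), and MECOM (-0.204) were negative. In all 597 of 12340 genes passed (592 positive), 79 with rescaled cells. There CXCL8 (-0.186, adjusted p = 0.0506) and MECOM (-0.192, adjusted p = 0.0365) kept similar values but missed a threshold.

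By list, 41 of 43 ribosomal, 13 of 13 mitochondrial and 16 of 33 oxidative phosphorylation genes correlated positively with the index, against 0, 0 and 1 with rescaled cells. In the excitation and neuromuscular junction list 5 of 14 did, and 5 with rescaled cells. No G2/M or S-phase gene passed. Of 12 relations of MYOD1 or a list index to the sarcomere index, here without removing the effect of genes detected, 0 passed by exact permutation (smallest adjusted p 0.0625; 6 relations at the smallest p for 6 cultures, 0.03125). MYOD1 itself gave a mean rho of 0.19 (r 0.164, 0.177 without the 2 farthest cells per culture), above 0 in 6 of 6 cultures. The insulin and IGF index gave 0.32 (rescaled 0.16), TGF-beta and smooth muscle 0.29 (0.19), ribosomal proteins 0.38 (0.012), interferon 0.23 (0.12), BMP and ID 0.19 (0.047), matrix 0.19 (0.0115), cholesterol 0.16 (0.0926), Notch 0.12 (-0.0333), immediate early 0.09 (-0.0246), G2/M 0.07 (0.0272) and S phase 0.07 (0.00147). The sign for Notch and immediate early turned with rescaled cells. With the effect of genes detected removed, G2/M gave -0.08, S phase -0.10 and immediate early -0.04, so their sign turned. By exact permutation, unadjusted, G2/M then sat at the smallest p, 0.03125, S phase at 0.0625 and immediate early at 0.406.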

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

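The weighings of the falls at 24 h, of the rescaling at 72 h and of the cells matched on genes detected were chosen only after the result was seen; the others were written down before their values.

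Among the 99 wells scored empty, 35 reached 500000 mapped fragments, a signal in wells that no comparison uses. Their median number of genes detected was 3618, against 6470 in the wells with 1 cell. All 8 of these wells from 48 and 72 h held ACTC1 and TNNT2. The score and the reads therefore do not separate empty from filled wells sharply, and whether these wells held a cell or carried-over RNA was not tested.

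The 93 falls at 24 h against 0 h were weighed in the run without the 3 atypical cells. It leaves out the 2 cells of the 0 h culture above 90% mitochondrial FPKM and 1 cell at 48 h. The 48 h cell enters this comparison only through the shared spread and the filter on low values. The median log2 change of the 93 genes went from -4.27 to 0.03 (0.03365, quartiles -0.44 to 0.48 over 78 tested genes), and 3 genes were still called. That meets what was predicted if the 2 cells at 0 h made the falls. If the medium and the induction made the falls, at least 80% was predicted to stay lower by at least 1, and 8.60% (8 of 93) did. That share comes from the same run, and genes not tested there count as not lower. It is thus no separate test and cannot exclude an effect of the medium or the induction. The 8 genes that stayed lower are left open. Why these 2 cells hold so much mitochondrial RNA was not tested.

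Most genes had a higher mean FPKM over cells at 72 h than at 24 h, with a median log2 change of 0.744. With the mean of log values the median was 0.0374, so the shift depends on averaging the cells before the log. After each cell was rescaled to the same total the median was 0.0477, as predicted for a difference in the scale of the deposited FPKM per cell. Rescaling takes out most of a shift shared by many genes, whatever its source. The outcome was thus nearly fixed in advance and gives no support to a cause. The test cannot tell a scale made by the quantification from one made by the cells, since no spike-in values or total RNA per cell are in the table. Cells above a sum of 2000000 did not make most of the shift by themselves. Without the 11 such cells, 1 at 24 h, 7 at 72 h and the rest at other times, the median was 0.623. It was 0.412 to 0.821 over the 4 pairs of cultures. High values in cells under that cut were not tested, so a part for them was not excluded. For fewer genes detected at 72 h, FPKM sums were compared among cells with 5500 to 6500 genes detected. The lowest ratio between a 72 h and a 24 h culture was 1.51, the highest 1.99. The sums thus differed at a like number of genes detected. The median change of all genes was not taken in these cells, so this explanation of it was not excluded.

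MYOG was detected in few cells at 72 h, while ACTC1 and TNNT2 were found in nearly all. Against genes with a like mean FPKM, its share lay at percentile 15.5 in 1 culture at 72 h and 3.72 in the other, which cannot tell low level and missed detection from a real restriction to few cells. Its mean rho with the sarcomere index was 0.197 (0.0307 to 0.343; 4 of 4 positive) over the 4 cultures at 48 and 72 h, since MYOG was at or near 0 at 24 h. That lies just under the 0.2 written down beforehand, and 4 cultures allow no exact p below 0.125, so this test cannot tell either.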

How the results depend on the processing

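The replicate block, cells rescaled, the filter and the other settings were planned; the run without the 3 atypical cells and the centred run were chosen only after the result was seen.

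Genes called at 24 h against 0 h (114) numbered 597 with no filter on low values, 19 with cells rescaled and 10 without the atypical cells, and 31 to 93 when 1 culture was left out. At 72 h against 0 h (974) the count was 329 rescaled, and 182 to 1399 with 1 culture left out. At 72 h against 24 h (790) it was 0 with no filter, 39 rescaled, 109 without a trend, 98 centred and 1244 with the replicate block, and 0 to 1277 with 1 culture left out. The block treats equal replicate numbers as pairs. Deviations of equally numbered cultures correlated at 0.177, 0.128 and 0.0979, low but all positive. Whether the numbers pair the cultures was thus not settled. At 48 h against 24 h (9) it was 0 with no filter, 0 rescaled, 0 without a trend, and 0 to 17 with 1 culture left out. At 72 h against 48 h (1) it was 0 with no filter, 0 rescaled, 2 with at least 1000000 fragments, and 0 to 0 with 1 culture left out. Leaving out a culture leaves fewer residual degrees of freedom, and no filter raises the genes tested to 29766; beyond that the cause was not tested.

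Lists called at 24 h against 0 h (11) numbered 0 with an estimated correlation and 2 with fry, and 9 to 10 with 1 culture left out. At 72 h against 24 h (13) they numbered 1 with an estimated correlation and 8 to 11 with 1 culture left out. Other settings gave 8 to 13 and 10 to 15. The cause was not tested.

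The share of cells with MYOG at 72 h (13.8%) was 17.7% at a threshold of 0.1, 11.2% at 10, 14.0% with at least 1000000 fragments, and 10.84 to 16.67% in single cultures. Genes correlated with the sarcomere index (597) numbered 326 with a pseudocount of 0.1, 79 rescaled, 1102 without removing the effect of genes detected, and 547 to 747 with 1 culture left out; the cause was not tested. The list relations stayed at 0 (0 to 0 with 1 culture left out), but the design nearly fixes this: with 6 cultures most of the 12 would have to sit at the smallest exact p, 0.03125, and with 5 none could pass.

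Genes that changed sign at 24 h against 0 h were EML5 (0.36), MT-ND2 (0.29), MT-ND4 (0.42), MTCO3P12 (0.0694) and NAPRT (1.59) without the atypical cells, MT-ND4 (0.0883) and NAPRT (0.49) with the mean of log values, and NAPRT (0.76) rescaled. At 72 h against 0 h SPATA13 (0.82) did so without the atypical cells. That run leaves out 2 of the 63 cells at 0 h by construction; for the mean of log values and the rescaling the cause was not tested.

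Of the named genes' values under other settings 516 kept direction and side of the threshold, 123 lost the threshold and 9 changed sign. With 1 culture left out 266 kept both and 124 lost the threshold. SH2D5 fell under the filter, so was not tested, rescaled or without the atypical cells. MYOG and CKM were found in few cells, and whether depth limited their detection was not settled.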

Other observations

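No test in this part was chosen only after the result was seen; values are given without an explanation.

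At 24 h 5 and 3 sarcomere genes were detected per cell (medians of the 2 cultures), against 2 at 0 h, 8 and 8 at 48 h, and 9 and 8 at 72 h, of 35. MYH3 was found in 34.9 ± 35.5% of cells at 24 h and 57.4% at 48 h, while TNNT2, a thin filament gene, was in 21.4% and 93.3%.

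DKK1 had a mean FPKM of 366 at 0 h, 14.9 ± 5.74 at 24 h and 3.08 at 48 h, so most of its level was gone by 24 h. The collagenase gene MMP1 stood at 734 at 0 h, 328 ± 52.9 at 24 h and 32.2 at 48 h. CDK1 had a mean FPKM of 71.6 at 0 h and 59.4 ± 45 at 72 h although the share of cells with it was 85.7% and 23.1%.

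Culture means correlated across genes at 0.912, 0.920 and 0.898 between the replicates at 24, 48 and 72 h, and lowest, 0.788, between 0 h and 72 h replicate 2. Replicates were not always the closest pairs: 24 h replicate 1 correlated with 48 h replicate 2 at 0.930, and 48 h replicate 1 with 72 h replicate 1 at 0.930. No pair of wells had identical values. Of the 25 wells with 2 cells, 22 reached the minimum of mapped fragments.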
